A study of Homo sapiens with 15 samples.

How the data were processed

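Gene expression was measured in 15 libraries of aggregates made from 1231A3, a human iPSC line, in 5 groups of 3 replicates: NCC aggregates at day 5, mdEM at day 9, distal cap and proximal-oral domains at day 13, and dental mesenchyme at day 17. Per the labels' protocols, total RNA was treated with DNase and 10 ng of it was made into a library with the Ion AmpliSeq Transcriptome panel, amplified for 13 cycles. The submitters' processing notes name the hg19 build and DESeq2, without a version; the aligner and the counting tool are not given in the sources used here, nor is whether counting used strand. The deposited table holds whole-number counts per gene, not normalized, per the file headers and the values, and its gene symbols are used as given. Each library's column was matched to its sample by title, and group and replicate number came from the same title.

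The table has 20812 entries. Of these, 10 are external control transcripts with 0 counts in all libraries and were left out, and 28 carry a calendar date in place of a symbol, hold at most 0.332% of a library's counts and stayed in the fits but are never named. Of the 20802 genes analysed, 1657 had no count in any library. Totals ran from 10385264 to 13799686 counts. The floor used here is 3 counts. By these totals, before scaling, it corresponds to 0.217 CPM in the deepest and 0.289 CPM in the shallowest library. The panel carries no molecular identifiers, so counting intervals and floors cover counting error only and not the spread from amplification.

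Tests ran in R 4.3.3. Genes were filtered with edgeR 4.0.16 (filterByExpr by group, its defaults), which kept 14294, scaled by TMM (factors 0.900 to 1.08) and tested with the edgeR quasi-likelihood F test, two-sided, with robust dispersions and 1 mean per group over all 15 libraries, so that the groups share 1 estimate of the spread. The common biological coefficient of variation was 20.0%. Genes were called at a Benjamini-Hochberg adjusted p under 0.05, and counts are also given for those changed at least 2-fold. CPM are computed here with TMM-scaled totals. Folds of called genes are fitted values. A fitted fold change depends on the prior count where a group is left without a count, so values without 1 library then show only that its counts came from that library. Where a group had no count, a fold is given as at least the ratio to 3 counts over that group, and where it had 1 to 3 counts, as the ratio of CPM from summed counts with its exact 95% counting interval.

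Gene lists were tested with camera of limma 3.58.1 on log2 CPM (prior count 2), two-sided, with the correlation between genes estimated for each list and adjustment over 140 tests, 28 lists in 5 comparisons. Of 29 lists written before the data were examined, the HOX cluster had fewer than 3 tested members and was not tested. The others were neural crest, ectomesenchyme, DLX and endothelin response, distal mandibular, proximal and oral mandibular, dental mesenchyme, odontoblast and osteoblast, cartilage, fibrillar matrix, smooth muscle, BMP, Hedgehog, FGF, WNT, activin and TGF-beta, and retinoic acid response, anterior neural identity, pluripotency, neuronal, Schwann and glial, melanocyte, epithelial, skeletal and cardiac muscle, endothelial, proliferation, hypoxia and glycolysis, cell stress, and cholesterol synthesis. Some share members, as the distal mandibular and DLX lists do. SC5D, SIX3 and HOXC4 were not analysed here. Some genes stay in the fits and list tests but are not reported here. A list's members are counted as called higher or lower over all genes and, with adjustment within the list, adjusted over the list alone. The list calls given hold with the estimated correlation; at a preset correlation of 0.01 camera called 18, 17, 14, 14 and 12 lists in the 5 comparisons.

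The 5 comparisons, the key genes of each, the lists, the tests and most alternatives were fixed before the data were examined. Named genes are the key genes, the 6 largest rises and 6 largest falls with a mean of at least 5 CPM over the 6 libraries compared, an adjusted p under 0.05 and no overlap between the groups' libraries, and up to 4 members of each list with the smallest adjusted p. Alternatives were RLE (DESeq2) and upper-quartile scaling, no filter, a stricter filter (at least 5 CPM in at least 3 libraries), DESeq2 1.42.0 (Wald test), limma-voom, the replicate number as a block, only the 6 libraries compared, leaving out each library in turn, the preset correlation, and fry. An added term for 2 classes of libraries, the block in 9 libraries and the fit of 10 libraries without replicate 2 were chosen after the data were seen. A list's range of adjusted p covers camera with the estimated correlation under RLE scaling, no filter, the blocks, each library left out, and the 10 libraries. Camera then takes its degrees of freedom from the residuals, which are fewer in the fits of 10 and 9 libraries. A list lost there is thus not shown to depend on replicate 2 or on the block.

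Same-numbered libraries deviated together from their group means between the distal cap and proximal-oral groups (correlations 0.263, 0.420 and 0.297 for replicates 1, 2 and 3) and between dental mesenchyme and proximal-oral groups (0.157, 0.382 and 0.258). All exceed 0.1, so the numbers were taken to pair the samples there, on the data and not on any statement in the labels. The comparisons with mdEM and NCC aggregates did not meet this rule. The deviations include an axis that separates replicate 2 in every group, with the opposite sign in mdEM. The correlations with mdEM thus do not show that the numbers mark nothing shared there, and NCC aggregates were compared with mdEM alone. Transcript GC content and length came from the GENCODE release 29 transcripts, per gene and not per amplicon, because the panel design was not available.

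The fits were tested on simulated counts drawn from the real means and library sizes, with 200 genes changed in each comparison. Of genes changed 1.5-fold, 2-fold and 4-fold, edgeR recovered 16.4%, 59.7% and 95.5% for mdEM against NCC aggregates (14129 genes), 7.46%, 64.2% and 93.9% for the distal cap against mdEM (14135 genes), 13.4%, 70.1% and 90.9% for proximal-oral aggregates against mdEM (14146 genes), 8.96%, 61.2% and 97.0% between the day 13 domains (14097 genes), and 10.4%, 65.7% and 90.9% for dental mesenchyme against proximal-oral aggregates (14116 genes). Genes left unchanged made up 6.36%, 4.32%, 4.09%, 4.82% and 4.27% of those called. Camera called all 4 lists shifted 4-fold and 0 of the others in each comparison. Genes were drawn independently here, so these lists lack the correlation between genes and the shared deviations of the real libraries. Libraries were drawn independently too, and fewer genes were changed than edgeR calls in the real data. No smaller shift of a list was tried, and adjustment covered the lists of each comparison alone. The power and error rate of the gene and list tests on the real data are thus not known from these simulations. For genes shared by the day 13 domains, a first set of simulations took the observed mdEM mean as the true one. It thus left out chance in the shared controls, and gave 0.5 and 0.650 genes at an unadjusted p under 0.05. The simulations reported draw the mdEM libraries too and were added after the first set was seen.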

Results

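The 15 libraries came from aggregates of 1231A3, a human induced pluripotent stem cell (iPSC) line, that were carried through successive culture media and read with Ion AmpliSeq Transcriptome, a targeted panel that amplifies a short stretch of each gene's transcript. They form 5 groups of 3 libraries: neural crest cell (NCC) aggregates at day 5, mandibular prominence ectomesenchyme (mdEM) at day 9, distal cap and proximal-oral domains of the mandibular mesenchyme at day 13, and dental mesenchyme at day 17. From day 5 to day 9 the mdEM medium held FGF8b at 100 ng/ml, endothelin-1 at 50 nM and BMP4 at 2.5 ng/ml. From day 9 the distal cap medium held endothelin-1 at 50 nM, FGF2 at 20 ng/ml and BMP4 at 25 ng/ml. The proximal-oral medium held FGF8b at 100 ng/ml, the Smoothened agonist SAG at 400 nM, the endothelin A receptor antagonist BQ-123 at 10 µM and the BMP receptor kinase inhibitor LDN193189 at 500 nM. Proximal-oral aggregates were moved at day 13 to a dental mesenchyme medium with FGF8b at 100 ng/ml, SAG at 400 nM, the GSK-3 inhibitor CHIR99021 at 3 µM and activin A at 30 ng/ml. Library totals ran from 10385264 to 13799686 counts. In all, 14294 of the 20802 genes analysed had enough counts to be tested. Values are CPM, counts scaled to the library total, given as mean ± SD with n = 3 libraries in every group. The labels do not say whether the libraries of a group came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

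Libraries grouped first by label: the share of variance between group means was 91.9% over the 2000 most variable genes. These genes were picked by their variance over the same libraries, which favours genes that differ between groups and so a high share. Component 1 held 48.6% of the variance and separated the NCC aggregates from the proximal-oral and dental libraries, and component 2 held 32.0% and set mdEM and the distal cap apart from the other groups. In each group, replicate 2 differed more from the other pair than these differed from each other. The chi-square of counts over genes, divided by its degrees of freedom, was 31.8 to 50.5 for the pairs with replicate 2 and 6.70 to 10.1 for replicates 1 and 3, so every pair differed by more than counting noise. These values include spread from amplification, so they do not show whether replicates 1 and 3 are separate samples, and the labels' 3 libraries per group were kept. The first component of the deviations from the group means, which separates replicate 2 in every group, held 32.2% of the variance within groups. In mdEM the sign was opposite: replicates 1 and 3 lay at 17.9 and 14.3, on the side of replicate 2 of the other groups. The sides are thus uneven between mdEM and the other groups. Without replicate 2 of every group, mdEM keeps libraries of 1 side and the other groups those of the other side. If the axis is shared between groups, comparisons with mdEM in that fit cannot be told apart from it. With all libraries, mdEM still has replicates 1 and 3 on the side where each other group has only replicate 2. The main comparisons with mdEM, and their counts of genes called, would then be partly mixed with the axis too.

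**Figure D1:**
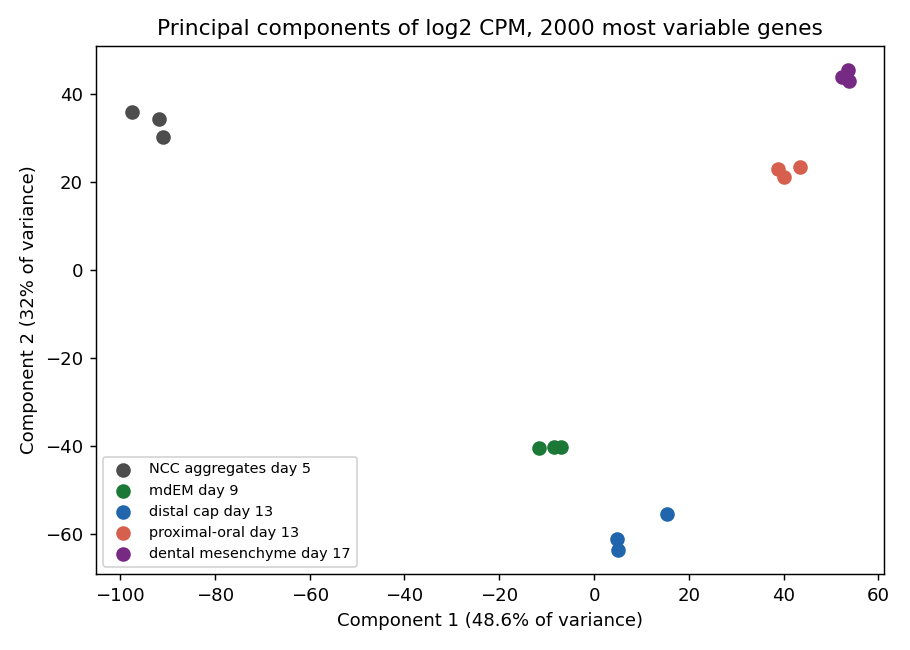
Principal components 1 (x axis, 48.6% of variance) and 2 (y axis, 32.0%) of log2 CPM over the 2000 most variable genes, 1 point per library, coloured by group. The 3 libraries of each group lie together, with NCC aggregates between -97.6 and -91.0 on component 1 and dental mesenchyme between 52.4 and 53.7.

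Neural crest genes fell and ectomesenchyme genes rose between the NCC aggregates of day 5 and the mdEM of day 9. This step asks how the aggregates responded to the mandibular medium. Here and in each later step the medium and the days in culture changed together, and no library holds aggregates kept in the earlier medium, so the 2 cannot be separated. SOX10, a regulator of neural crest and glial cells, fell 22.1-fold from 674 ± 144 to 30.4 ± 2.79 CPM. FOXD3, which marks premigratory neural crest, fell 105-fold from 153 ± 16.5 to 1.45 ± 1.10 CPM. TWIST1, a mesenchymal transcription factor, rose 73.5-fold from 5.15 ± 1.61 to 378 ± 132 CPM. The growth factor receptor gene PDGFRA rose 19.5-fold from 34.6 ± 10.6 to 676 ± 106 CPM. HAND2, which acts downstream of endothelin in the ventral arch, reached 486 ± 99.7 CPM from 1 count over the NCC libraries, a ratio of 16972 (95% counting interval 3046 to 670379) (the log2 fold change was 13.61 and 15.55 without NCC replicate 1). DLX5, one of the DLX genes that pattern the arches from proximal to distal, rose from 6.88 ± 3.02 to 159.9 ± 45.9 CPM.

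The neural crest list had 0 of 16 tested members higher and 13 lower over all genes, and 0 and 14 adjusted over the list alone. It passed the list test (camera adjusted p = 0.0238), but not without replicate 2 of every group (0.140) or with the replicate number as a block (0.0538). The fit without replicate 2 has fewer residual degrees of freedom, from which camera takes its own. Here and below, a list lost in that fit is thus not shown to depend on replicate 2. TFAP2B fell from 561 ± 38.7 to 85.1 ± 12.0 CPM. PAX3 fell from 338 ± 13.5 to 81.8 ± 5.65 CPM and the neurotrophin receptor gene NGFR from 191 ± 79.2 to 11.2 ± 8.63 CPM (the log2 fold change was -4.09 and -4.78 without mdEM replicate 3). TFAP2A was at 393 ± 49.6 CPM in NCC aggregates and 282 ± 53.9 CPM in mdEM (edgeR adjusted p = 0.0973, 0.0443 without mdEM replicate 2, 1.10e-04 without replicate 2 of every group, 1.10e-04 to 0.280 over its alternatives). The Schwann and glial list, which shares members such as SOX10 and ERBB3 with the neural crest list, had 1 of 8 tested members higher and 6 lower over all genes, and 1 and 6 adjusted over the list alone (camera adjusted p = 0.123). S100B fell from 99.6 ± 3.57 to 1.45 ± 0.576 CPM. The ectomesenchyme list had 10 of 10 tested members higher and 0 lower over all genes, and 10 and 0 adjusted over the list alone, and passed (camera adjusted p = 0.0238), but not without replicate 2 of every group (0.140). FOXC1 rose from 1.76 ± 0.601 to 92.1 ± 5.61 CPM. The cadherin gene CDH11 rose from 40.9 ± 4.33 to 418 ± 13.4 CPM. PRRX1 reached 13.99 ± 10.0 CPM at a ratio of 489 (95% counting interval 87.4 to 19359) (the log2 fold change was 8.49 and 10.43 without NCC replicate 1 and 7.74 without mdEM replicate 2).

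The list of DLX and endothelin response genes had 9 of 12 tested members higher and 2 lower over all genes, and 9 and 2 adjusted over the list alone (camera adjusted p = 0.104). DLX1 rose from 6.25 ± 2.15 to 193 ± 18.2 CPM. DLX2 rose from 38.0 ± 15.3 to 195 ± 17.7 CPM and DLX6 from 0.479 ± 0.580 to 120.2 ± 25.4 CPM (the log2 fold change was 7.92 and 9.38 without NCC replicate 1). The endothelin receptor gene EDNRA fell from 831 ± 163 to 202 ± 28.8 CPM. HAND1 was lower in mdEM at 3 counts over the group, a ratio of 6.78 (95% counting interval 2.03 to 35.5), and the log2 fold change was -2.62 and -1.82 without NCC replicate 1. It was called (edgeR adjusted p = 0.0188) but not without NCC replicate 1 (0.116), mdEM replicate 1 (0.0531) or mdEM replicate 3 (0.0526), nor with limma-voom (0.0954), in a range of 0.00197 to 0.116 over its alternatives. The distal mandibular list had 10 of 14 tested members higher and 3 lower over all genes, and 10 and 3 adjusted over the list alone (camera adjusted p = 0.133). The proximal and oral mandibular list had 5 of 11 tested members higher and 0 lower over all genes, and 6 and 0 adjusted over the list alone (camera adjusted p = 0.0417). The dental mesenchyme list, which shares BARX1, LHX6, LHX8, OSR2 and PAX9 with it, had 8 of 15 tested members higher and 1 lower over all genes, and 9 and 1 adjusted over the list alone (camera adjusted p = 0.0497). Both passed, but not without replicate 2 of every group (0.203 for both) or with the replicate number as a block (0.0557 and 0.0837). Nor did they pass without any 1 of several single libraries, given below. BARX1, a mesenchymal homeobox gene of the maxillary and mandibular arch, had no count in the NCC libraries and was at least 1803-fold higher in mdEM at 155 ± 7.59 CPM. Among response genes, the FGF list had 11 of 14 tested members higher and 1 lower over all genes, and 11 and 1 adjusted over the list alone (camera adjusted p = 0.0658). DUSP6 rose from 6.10 ± 1.55 to 157 ± 36.3 CPM. The fibrillar matrix list had 12 of 14 tested members higher and 0 lower over all genes, and 13 and 0 adjusted over the list alone (camera adjusted p = 0.0537). COL1A1 rose from 9.28 ± 0.807 to 409 ± 51.3 CPM.

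The largest rises besides HAND2 and BARX1 were those of NBLA00301, MECOM and COL24A1, all without a count in NCC libraries and at least 1317-fold, 229-fold and 186-fold higher, and of SYNPO at a ratio of 1451 (95% counting interval 260.0 to 57345). PCDH8 fell from 15.0 ± 7.31 CPM to no count, at least 175-fold lower. The neural crest gene PAX7 and the midbrain gene DMBX1 were lower at ratios of 308 (95% counting interval 85.0 to 2550.2) and 337 (95% counting interval 93.0 to 2790.3). SP5 and FAM198A were lower at ratios of 675 (95% counting interval 121 to 26717) and 405 (95% counting interval 72.3 to 16038). PRDM12 fell from 69.8 ± 27.1 to 0.382 ± 0.304 CPM. Leaving out 1 library moved these fold changes by more than 1.5 times, on the log2 scale: SYNPO was 10.06 and 11.99 without NCC replicate 3, PAX7 was -8.05 and -10.80 without mdEM replicate 1, SP5 was -9.03 and -7.91 without NCC replicate 2 and -10.99 without mdEM replicate 3, FAM198A was -8.23 and -10.19 without mdEM replicate 3, PRDM12 was -7.47 and -8.22 without mdEM replicate 1. In these genes, as in the largest changes of the other comparisons, the 3 libraries of 1 group all lay above the 3 of the other, a separation that chance gives in 10% of genes.

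edgeR called 5271 of 14294 genes at an adjusted p under 0.05, 2910 higher and 2361 lower in mdEM. Of these, 3008 changed at least 2-fold, 1879 up and 1129 down. Camera called 4 of 28 lists. The dental mesenchyme list did not pass without NCC replicate 2 (0.0655), NCC replicate 3 (0.0663), mdEM replicate 1 (0.0563), mdEM replicate 2 (0.0784), distal cap replicate 1 (0.0626) or 2 (0.0505), proximal-oral replicate 3 (0.0553), or dental mesenchyme replicate 1 (0.0632), 2 (0.0549) or 3 (0.0538). The proximal and oral list did not pass without NCC replicate 2 (0.0655), NCC replicate 3 (0.0599), mdEM replicate 1 (0.0516), mdEM replicate 2 (0.0623), distal cap replicate 1 (0.0508), proximal-oral replicate 3 (0.0553), or dental mesenchyme replicate 1 (0.0541) or 2 (0.0549). Over their alternatives the camera adjusted p ran from 0.0243 to 0.203 for the dental list and from 0.0267 to 0.203 for the proximal and oral list. Without NCC replicate 1 the DLX and endothelin response (0.0173), distal mandibular (0.0182) and fibrillar matrix (0.0406) lists passed, as did fibrillar matrix without distal cap replicate 2 (0.0393) and FGF response without proximal-oral replicate 2 (0.0184). With no filter on low counts fibrillar matrix (0.0357) and FGF response (0.0443) also passed. The ranges of these 4 lists were 0.0173 to 0.382, 0.0182 to 0.410, 0.0357 to 0.140 and 0.0184 to 0.140. With replicate 2 of every group left out, a choice made after the data were seen, this comparison cannot be told apart from the replicate 2 axis. That fit called 7815 genes by edgeR and 0 lists by camera. There were 10 lists at an unadjusted p under 0.05, with 15 called at the preset correlation and 26 by fry.

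Distal cap aggregates of day 13 had higher HAND1 and endothelial genes than the mdEM they were grown from, and lower cholesterol synthesis genes. This comparison asks what changed in the distal medium, with its higher BMP4 and its FGF2 in place of FGF8b, and over 4 further days, which cannot be separated. HAND1, a marker of the distal arch, rose from 3 counts over the mdEM libraries to 55.2 ± 9.15 CPM, a ratio of 623 (95% counting interval 213 to 3023). GATA3 rose from 8.85 ± 1.35 to 43.0 ± 7.82 CPM and the BMP antagonist gene BAMBI from 78.9 ± 15.0 to 348 ± 83.6 CPM. HMGCS1, an early enzyme of sterol synthesis, fell 5.15-fold from 392 ± 40.6 to 76.1 ± 7.41 CPM. KDR, a VEGF receptor gene of endothelial cells, rose 7.995-fold from 9.43 ± 1.37 to 75.5 ± 37.5 CPM.

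The distal mandibular list had 4 of 14 tested members higher and 3 lower over all genes, and 6 and 3 adjusted over the list alone (camera adjusted p = 0.754). DLX5 fell from 159.9 ± 45.9 to 53.8 ± 2.56 CPM and DLX6 from 120.2 ± 25.4 to 30.2 ± 15.1 CPM. The DLX and endothelin response list had 2 of 12 tested members higher and 4 lower over all genes, and 2 and 6 adjusted over the list alone (camera adjusted p = 0.669). Not called were HAND2 at 486 ± 99.7 and 421 ± 31.3 CPM in mdEM and distal cap, ID1 at 304 ± 94.0 and 280.1 ± 49.2 CPM, MSX1 at 55.0 ± 11.9 and 93.1 ± 24.5 CPM, MSX2 at 283 ± 21.4 and 419 ± 10.5 CPM, and ALX4 at 21.2 ± 3.10 and 13.1 ± 1.21 CPM. MSX1 (edgeR adjusted p = 0.0920) was called without distal cap replicate 2 (0.0418), dental mesenchyme replicate 2 (0.0234) or replicate 2 of every group (1.63e-06), in a range of 1.63e-06 to 0.262 over its alternatives. ALX4 (0.140) was called without proximal-oral replicate 2 (0.0330) or replicate 2 of every group (0.00180), with limma-voom (0.0406) and with only the 6 libraries compared (0.0374), in a range of 0.00180 to 0.332, and MSX2 (0.316) with only the 6 libraries compared (0.0233), in a range of 0.0233 to 0.483.

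The BMP response list had 7 of 10 tested members higher and 0 lower over all genes, and 7 and 0 adjusted over the list alone (camera adjusted p = 0.123). SMAD6, which inhibits BMP signalling, rose from 17.3 ± 1.63 to 79.2 ± 5.36 CPM. The list passed without NCC replicate 1 (0.0406), in a range of 0.0406 to 0.342. The endothelial list had 5 of 6 tested members higher and 0 lower over all genes, and 6 and 0 adjusted over the list alone and passed (camera adjusted p = 0.0254), though not without mdEM replicate 2 (0.0637) or without replicate 2 of every group (0.192), in a range of 0.0209 to 0.192. The cadherin gene CDH5 rose from 3.40 ± 1.75 to 28.6 ± 16.5 CPM and the angiopoietin receptor gene TEK from 7.20 ± 3.59 to 21.8 ± 6.30 CPM. The cholesterol synthesis list had 0 of 10 tested members higher and 10 lower over all genes, and 0 and 10 adjusted over the list alone and passed (camera adjusted p = 0.0238), but not without replicate 2 of every group (0.140). In the proliferation list there were 0 of 19 tested members higher and 16 lower over all genes, and 0 and 18 adjusted over the list alone (camera adjusted p = 0.0781). TOP2A fell from 467 ± 21.0 to 220.4 ± 24.8 CPM. Smooth muscle genes counted 5 of 9 tested members higher and 0 lower over all genes, and 6 and 0 adjusted over the list alone (camera adjusted p = 0.0888, 0.0471 with the replicate block, 0.0471 to 0.203 over its alternatives). TAGLN rose from 8.27 ± 4.03 to 99.2 ± 42.4 CPM and the coactivator gene MYOCD from 1.15 ± 0.386 to 8.91 ± 0.927 CPM. The fibrillar matrix list counted 8 of 14 tested members higher and 0 lower over all genes, and 8 and 0 adjusted over the list alone (camera adjusted p = 0.112). COL3A1 rose from 61.6 ± 35.9 to 698 ± 363 CPM. The skeletal and cardiac muscle list counted 3 of 5 tested members higher and 0 lower over all genes, and 3 and 0 adjusted over the list alone (camera adjusted p = 0.133). The cardiac actin gene ACTC1 rose from 14.8 ± 2.04 to 101 ± 54.2 CPM.

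The largest rises besides HAND1 were those of BMP6, to 16.5 ± 20.4 CPM, C12orf69, to 16.0 ± 11.3 CPM, the endoderm and heart regulator GATA6, from 0.207 ± 0.102 to 14.8 ± 5.10 CPM, F13A1, to 16.3 ± 11.8 CPM, and THBS1, from 5.95 ± 3.39 to 246 ± 169.9 CPM. Among the largest falls were those of PI15, from 168 ± 65.2 to 9.66 ± 0.978 CPM, BARX1, from 155 ± 7.59 to 11.0 ± 0.612 CPM, SMOC1, from 21.5 ± 5.30 to 2.12 ± 0.441 CPM, FIGF, from 43.0 ± 8.39 to 4.90 ± 3.79 CPM, and LYPD6B, from 10.3 ± 2.13 to 1.80 ± 0.286 CPM. Leaving out 1 library moved these fold changes by more than 1.5 times, on the log2 scale: BMP6 was 6.70 and 7.36 without mdEM replicate 1 and 4.90 without distal cap replicate 2, C12orf69 was 6.66 and 7.35 without mdEM replicate 3 and 5.90 without distal cap replicate 2, F13A1 was 5.48 and 4.73 without distal cap replicate 2, THBS1 was 5.37 and 4.64 without distal cap replicate 2, FIGF was -3.14 and -3.98 without distal cap replicate 2.

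edgeR called 2176 genes, 1307 higher and 869 lower in the distal cap. Of these, 1142 changed at least 2-fold (896 up, 246 down). Camera called 2 of 28 lists. Fewer were called without mdEM replicate 1 (1430 genes), distal cap replicate 1 (1394) or distal cap replicate 3 (1441), and more with a term for 2 classes of libraries (3334). With replicate 2 of every group left out this comparison cannot be told apart from the replicate 2 axis. That fit called 6197 genes by edgeR, 1740 of them at least 2-fold, and 0 lists by camera. There were 5 lists at an unadjusted p under 0.05, with 12 called at the preset correlation and 19 by fry.

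Proximal-oral aggregates of day 13 had higher Hedgehog target and oral mesenchyme genes than mdEM, and lower ID1 and HAND2. This comparison asks what changed in the proximal-oral medium, with its Smoothened agonist and BMP and endothelin receptor inhibitors, and over 4 further days, which cannot be separated. PTCH1, the Hedgehog receptor and a direct target of the pathway, rose 13.98-fold from 29.6 ± 5.17 to 414 ± 92.7 CPM. GLI1, a further direct target, rose 218-fold from 0.148 ± 0.0532 to 34.4 ± 12.2 CPM. BARX1 rose 3.85-fold from 155 ± 7.59 to 596 ± 25.2 CPM. LHX8 rose 10.5-fold from 7.08 ± 1.19 to 74.8 ± 20.1 CPM and LHX6 from 0.176 ± 0.177 to 28.9 ± 6.55 CPM (the log2 fold change was 7.27 and 8.19 without mdEM replicate 2). ID1, a direct BMP target, fell 22.1-fold from 304 ± 94.0 to 13.8 ± 1.65 CPM. HAND2 fell 7.86-fold from 486 ± 99.7 to 61.9 ± 10.5 CPM and MSX1 fell 57.8-fold from 55.0 ± 11.9 to 0.941 ± 0.0156 CPM.

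The Hedgehog response list had 7 of 7 tested members higher and 0 lower over all genes, and 7 and 0 adjusted over the list alone (camera adjusted p = 0.00257) and passed, but not without replicate 2 of every group (0.140). HHIP rose from 0.327 ± 0.191 to 29.7 ± 5.10 CPM and the forkhead gene FOXF2 from 0.266 ± 0.307 to 53.6 ± 3.42 CPM (the log2 fold change was 7.60 and 9.08 without mdEM replicate 2). FOXF1, without a count in mdEM, was at least 201-fold higher at 17.6 ± 3.05 CPM. The proximal and oral mandibular list had 10 of 11 tested members higher and 1 lower over all genes, and 10 and 1 adjusted over the list alone (camera adjusted p = 0.00166) and passed. The dental mesenchyme list also passed, with 10 of 15 tested members higher and 1 lower over all genes, and 10 and 1 adjusted over the list alone (camera adjusted p = 0.0238). Neither passed without replicate 2 of every group (0.140). PITX1 rose from 0.207 ± 0.0515 to 10.3 ± 0.968 CPM. The tooth and palate gene PAX9 reached 8.25 ± 2.50 CPM from 1 count over the mdEM libraries, a ratio of 286 (95% counting interval 51.0 to 11332) (the log2 fold change was 7.70 and 9.66 without mdEM replicate 2). RUNX2 rose from 1.89 ± 0.670 to 18.1 ± 4.22 CPM. GSC fell from 45.7 ± 15.7 to 25.9 ± 7.83 CPM (edgeR adjusted p = 0.0458), but was not called without NCC replicate 1 (0.0555), 2 (0.0505) or 3 (0.0508), mdEM replicate 2 (0.199) or 3 (0.0737), distal cap replicate 1 (0.0549) or 3 (0.0560), proximal-oral replicate 1 (0.0914) or 3 (0.202), or dental mesenchyme replicate 1 (0.0557), nor with the stricter filter (0.0540) or only the 6 libraries compared (0.0929). Over its alternatives that p ran from 0.0121 to 0.202.

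The BMP response list had 0 of 10 tested members higher and 7 lower over all genes, and 0 and 7 adjusted over the list alone (camera adjusted p = 0.0734, 0.0243 without NCC replicate 1, 0.0243 to 0.255 over its alternatives). BAMBI fell from 78.9 ± 15.0 to 20.1 ± 2.05 CPM. The distal mandibular list had 2 of 14 tested members higher and 7 lower over all genes, and 2 and 8 adjusted over the list alone (camera adjusted p = 0.148, 0.0291 without NCC replicate 1, 0.0291 to 0.410 over its alternatives). GATA3 fell from 8.85 ± 1.35 to 0.193 ± 0.104 CPM. The FGF response list had 4 of 14 tested members higher and 2 lower over all genes, and 6 and 2 adjusted over the list alone (camera adjusted p = 0.566). DUSP6, a feedback phosphatase of FGF signalling, fell from 157 ± 36.3 to 82.6 ± 15.1 CPM. The WNT response list had 6 of 12 tested members higher and 1 lower over all genes, and 8 and 1 adjusted over the list alone (camera adjusted p = 0.154). APCDD1 rose from 12.9 ± 2.21 to 164 ± 39.3 CPM and NKD2 from 2.54 ± 0.531 to 44.9 ± 5.32 CPM. In the cartilage list there were 9 of 15 tested members higher and 1 lower over all genes, and 9 and 1 adjusted over the list alone (camera adjusted p = 0.0781). COL9A1 rose from 11.2 ± 2.53 to 42.5 ± 3.87 CPM. The cartilage list passed without NCC replicate 1 (0.0448) or dental mesenchyme replicate 2 (0.0413), and with no filter (0.0443), in a range of 0.0413 to 0.203. Hypoxia and glycolysis genes counted 11 of 14 tested members higher and 0 lower over all genes, and 12 and 0 adjusted over the list alone (camera adjusted p = 0.239, 0.0304 without distal cap replicate 2, 0.0304 to 0.345 over its alternatives). The glucose transporter gene SLC2A1 rose from 64.9 ± 9.65 to 294 ± 84.9 CPM. The anterior neural identity list counted 5 of 8 tested members higher and 0 lower over all genes, and 6 and 0 adjusted over the list alone (camera adjusted p = 0.0781, 0.0432 without proximal-oral replicate 1, 0.0432 to 0.268 over its alternatives). EN2 rose from 0.528 ± 0.295 to 3.21 ± 0.857 CPM.

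SIM2 rose from 0.265 ± 0.0852 to 311 ± 26.8 CPM and EGFL6 from 0.175 ± 0.149 to 285 ± 45.2 CPM, among the largest rises. OGN, without a count in mdEM, was at least 1272-fold higher at 119.6 ± 89.6 CPM. FOXD1, a target of Hedgehog signalling in facial mesenchyme, was higher at a ratio of 1339 (95% counting interval 370.4 to 11064) and the tendon regulator MKX at a ratio of 728 (95% counting interval 130.2 to 28779). The largest falls besides MSX1 were those of OLFM3, from 68.4 ± 28.7 to 1.20 ± 0.601 CPM, A2M, from 369 ± 102 to 7.99 ± 3.11 CPM, PALMD, from 37.4 ± 6.84 to 1.39 ± 0.427 CPM, TTC29, from 13.4 ± 1.35 to 0.502 ± 0.228 CPM, and CYP1A1, a target of the aryl hydrocarbon receptor, from 13.8 ± 3.32 to 0.202 ± 0.175 CPM. For EGFL6 the log2 fold change was 10.57 and 11.48 without mdEM replicate 1, for MKX the log2 fold change was 9.06 and 11.02 without mdEM replicate 1, and the proximal-oral libraries held OGN at 72.0, 223 and 63.7 CPM.

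edgeR called 2458 genes, 1425 higher and 1033 lower in proximal-oral aggregates. Of these, 1491 changed at least 2-fold (958 up, 533 down). Camera called 3 of 28 lists. With replicate 2 of every group left out this comparison cannot be told apart from the replicate 2 axis. That fit called 6110 genes by edgeR and 0 lists by camera. There were 3 lists at an unadjusted p under 0.05, with 11 called at the preset correlation and 26 by fry.

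**Figure D2:**
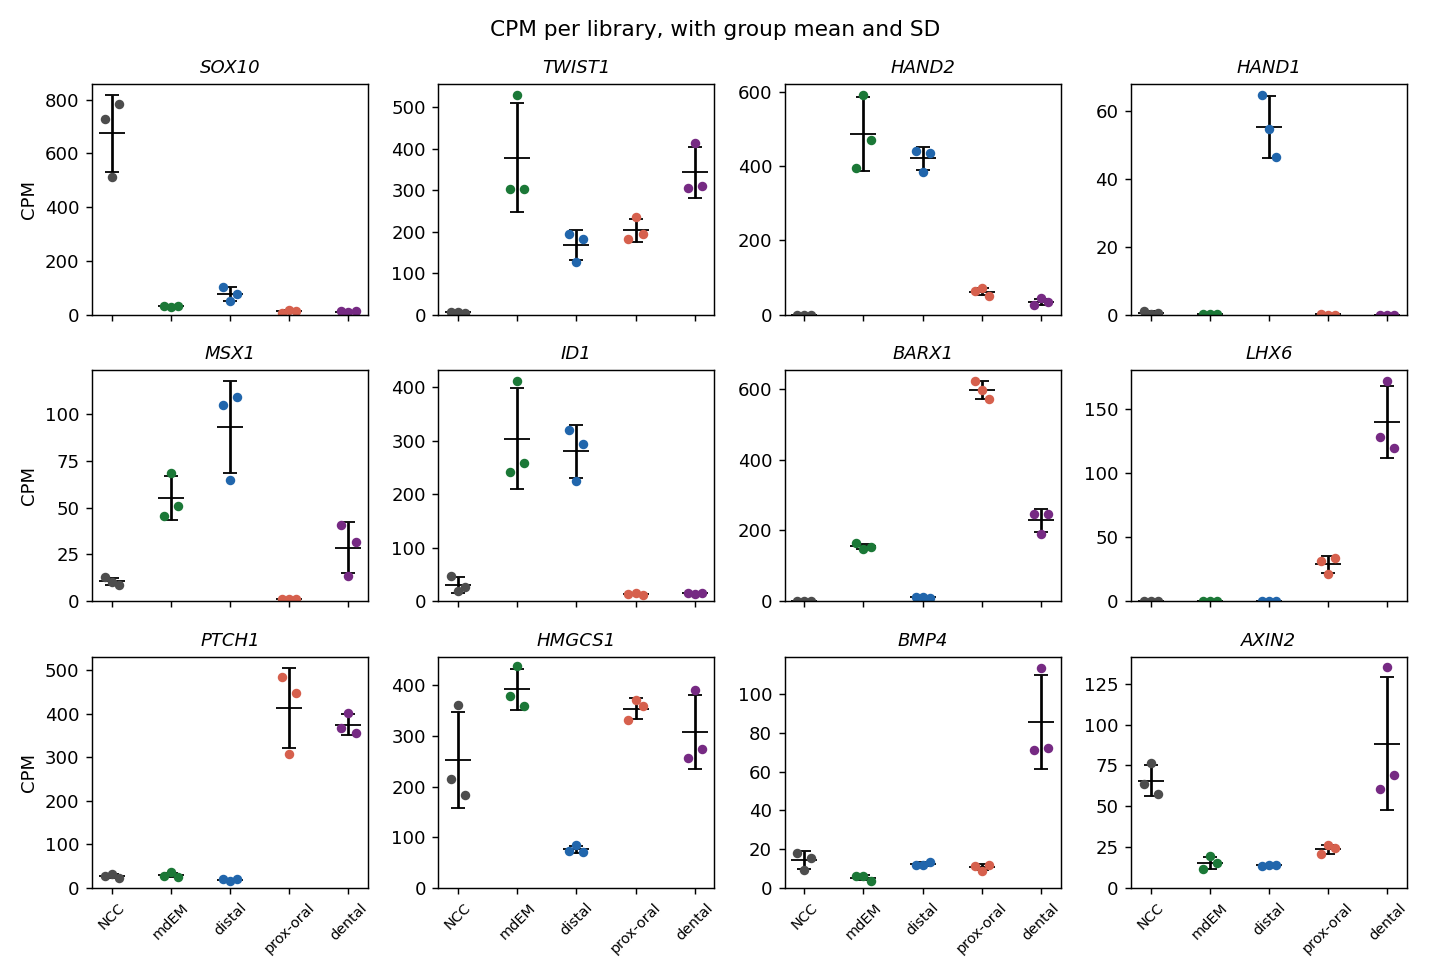
CPM (y axis, linear, from 0) of 12 genes in each of the 15 libraries (points), by group (x axis), with the group mean (bar) and SD (whiskers), n = 3. HAND1 was at 55.2 ± 9.15 CPM in distal cap and PTCH1 at 414 ± 92.7 CPM in proximal-oral aggregates.

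At the same age, the distal cap had lower proximal and oral mandibular genes than proximal-oral aggregates, and higher HAND2 and MSX1. This comparison asks how far the alternative media moved the same starting aggregates apart. HAND2 was 6.80-fold higher in the distal cap, at 421 ± 31.3 against 61.9 ± 10.5 CPM, and MSX1 97.9-fold higher at 93.1 ± 24.5 against 0.941 ± 0.0156 CPM. HAND1, with 1 count over the proximal-oral libraries, was higher at a ratio of 2052 (95% counting interval 368 to 81086) (the log2 fold change was 10.54 and 12.38 without proximal-oral replicate 1). BARX1 was 54.1-fold lower in the distal cap, at 11.0 ± 0.612 against 596 ± 25.2 CPM, and PTCH1 22.0-fold lower, at 18.8 ± 2.20 against 414 ± 92.7 CPM. ID1 was 20.4-fold higher, at 280.1 ± 49.2 against 13.8 ± 1.65 CPM.

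In the distal mandibular list there were 8 of 14 tested members higher and 2 lower over all genes, and 8 and 2 adjusted over the list alone (camera adjusted p = 0.154, 0.0298 without NCC replicate 1, 0.0298 to 0.397 over its alternatives). MSX2 was higher at 419 ± 10.5 against 120.4 ± 10.9 CPM, GATA3 at 43.0 ± 7.82 against 0.193 ± 0.104 CPM and ALX4 at 13.1 ± 1.21 against 3.71 ± 2.36 CPM (the log2 fold change was 1.84 and 2.48 without proximal-oral replicate 2). DLX5 was lower at 53.8 ± 2.56 against 175 ± 58.6 CPM and DLX6 at 30.2 ± 15.1 against 153 ± 73.2 CPM. DLX3 was higher at 30.1 ± 8.07 against 15.7 ± 1.65 CPM (edgeR adjusted p = 0.0205), but not called without distal cap replicate 1 (0.0894) or 3 (0.0724) or proximal-oral replicate 2 (0.0588) or 3 (0.0694), in a range of 1.54e-04 to 0.0894. GSC was higher at 47.6 ± 9.39 against 25.9 ± 7.83 CPM (edgeR adjusted p = 0.0247), but not called without distal cap replicate 2 (0.0926) or proximal-oral replicate 1 (0.0546) or 3 (0.128), in a range of 0.00253 to 0.128.

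The proximal and oral mandibular list had 1 of 11 tested members higher and 10 lower over all genes, and 1 and 10 adjusted over the list alone (camera adjusted p = 0.00166). The dental mesenchyme list had 1 of 15 tested members higher and 11 lower over all genes, and 1 and 11 adjusted over the list alone (camera adjusted p = 0.0238). Both passed, but neither did with the replicate number as a block in the 9 day 13 and day 17 libraries (0.194) or without replicate 2 of every group (0.140). LHX6 was at 0.346 ± 0.177 against 28.9 ± 6.55 CPM, LHX8 at 9.86 ± 2.98 against 74.8 ± 20.1 CPM and PITX1 at 0.0949 ± 0.0822 against 10.3 ± 0.968 CPM. PAX9, without a count in the distal cap, was at least 121-fold lower there. The Hedgehog response list had 0 of 7 tested members higher and 7 lower over all genes, and 0 and 7 adjusted over the list alone and passed (camera adjusted p = 0.00377), but not with that block (0.194) or without replicate 2 of every group (0.140). GLI1 was at 0.463 ± 0.187 against 34.4 ± 12.2 CPM, FOXF2 at 0.634 ± 0.260 against 53.6 ± 3.42 CPM and FOXF1 lower at a ratio of 382 (95% counting interval 105 to 3158). In the BMP response list, which passed (camera adjusted p = 0.0266), there were 10 of 10 tested members higher and 0 lower over all genes, and 10 and 0 adjusted over the list alone. It did not pass without mdEM replicate 2 (0.0539), with that block (0.194) or without replicate 2 of every group (0.192), in a range of 0.0101 to 0.194. BAMBI was at 348 ± 83.6 against 20.1 ± 2.05 CPM and ID3 at 29.4 ± 9.15 against 1.99 ± 0.280 CPM. The FGF response list had 3 of 14 tested members higher and 5 lower over all genes, and 3 and 5 adjusted over the list alone (camera adjusted p = 0.439). DUSP6 at 62.2 ± 4.83 against 82.6 ± 15.1 CPM and SPRY4 at 2.33 ± 0.692 against 2.81 ± 1.84 CPM were not called, but DUSP6 (edgeR adjusted p = 0.166) was without replicate 2 of every group (1.24e-04), in a range of 1.24e-04 to 0.406.

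The endothelial list passed (camera adjusted p = 0.0238) with 6 of 6 tested members higher and 0 lower over all genes, and 6 and 0 adjusted over the list alone. It did not pass with the block in 9 libraries (0.194) or without replicate 2 of every group (0.140). KDR was at 75.5 ± 37.5 against 7.86 ± 2.62 CPM and TIE1 at 36.1 ± 3.43 against 3.43 ± 1.76 CPM. The cholesterol synthesis list passed (camera adjusted p = 0.0270, 0.0660 with the replicate block, 0.194 with the block in 9 libraries, 0.140 without replicate 2 of every group, 0.0243 to 0.194 over its alternatives) with 0 of 10 tested members higher and 10 lower over all genes, and 0 and 10 adjusted over the list alone. INSIG1, a sterol-regulated brake on the pathway, was at 8.30 ± 0.438 against 41.3 ± 7.55 CPM. The proliferation list counted 0 of 19 tested members higher and 18 lower over all genes, and 0 and 19 adjusted over the list alone (camera adjusted p = 0.102). The proliferation marker MKI67 was at 106 ± 17.5 against 425 ± 139.9 CPM. The smooth muscle list counted 6 of 9 tested members higher and 0 lower over all genes, and 6 and 0 adjusted over the list alone (camera adjusted p = 0.0781, 0.0471 with the replicate block, 0.0471 to 0.203 over its alternatives). The hypoxia and glycolysis list counted 0 of 14 tested members higher and 4 lower over all genes, and 0 and 4 adjusted over the list alone (camera adjusted p = 0.531, 0.0450 without distal cap replicate 2, 0.0450 to 0.683 over its alternatives).

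Besides HAND1, the largest differences towards the distal cap were in CDC20B, GATA4 and GATA5, without a count in proximal-oral libraries and at least 433-fold, 275-fold and 136-fold higher at 34.9 ± 2.45, 22.4 ± 6.98 and 11.0 ± 1.36 CPM. The heart regulators TBX20 and GATA6 were higher at ratios of 875 (95% counting interval 242 to 7227) and 546 (95% counting interval 97.6 to 21581). Towards the proximal-oral aggregates the largest were in SIM2, at 0.160 ± 0.217 against 311 ± 26.8 CPM, OGN, at 0.146 ± 0.253 against 119.6 ± 89.6 CPM, FOXD1, at 0.190 ± 0.183 against 78.1 ± 13.4 CPM, EGFL6, at 0.836 ± 0.867 against 285 ± 45.2 CPM, and MKX, lower in the distal cap at a ratio of 921 (95% counting interval 165 to 36432). Leaving out 1 library moved these fold changes by more than 1.5 times, on the log2 scale: TBX20 was 9.52 and 12.17 without proximal-oral replicate 2, GATA6 was 8.64 and 10.48 without proximal-oral replicate 3, SIM2 was -10.81 and -12.72 without distal cap replicate 3, OGN was -9.63 and -13.49 without distal cap replicate 2 and -8.82 without proximal-oral replicate 2, FOXD1 was -8.63 and -9.43 without distal cap replicate 2, EGFL6 was -8.42 and -9.66 without distal cap replicate 2, MKX was -9.30 and -11.00 without distal cap replicate 2.

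edgeR called 3324 genes, 1657 higher and 1667 lower in the distal cap. Of these, 2091 differed at least 2-fold (1139 up, 952 down). Camera called 6 of 28 lists. With the replicate number as a block in the 9 day 13 and day 17 libraries alone edgeR called 4950 genes and camera 0 lists in this comparison (smallest adjusted p = 0.194, 9 lists at an unadjusted p under 0.05). With replicate 2 of every group left out edgeR called 5629 genes and camera 0 lists. There were 9 lists at an unadjusted p under 0.05, with 15 called at the preset correlation and 23 by fry.

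From the shared mdEM starting point, 539 genes were called in the same direction in both domains, 365 higher and 174 lower, where independent lists of these sizes would share 193 in all (130.3 and 62.8). Opposite calls were made for 227 genes, of which 152 were higher in the distal cap and lower in proximal-oral aggregates and 75 the reverse, where independent lists would share 181 (94.5 and 86.6). HAND1, BAMBI and GATA3 were higher in the distal cap comparison, and BAMBI and GATA3 lower in the proximal-oral one, while BARX1 fell in the first and rose in the second. In 20 simulations of unchanged groups, with the shared mdEM libraries drawn as well, edgeR gave 0 such genes in either class. No gene was changed in them, so adjustment leaves almost no calls and this 0 follows from the setting. At an unadjusted p under 0.05 it gave on average 145.2 in the same and 0.5 in opposite directions. With a deviation shared by same-numbered day 13 libraries the counts were again 0 by edgeR, and 225 and 0.05 unadjusted. Neither setting holds a deviation shared with the mdEM libraries, and the unadjusted overlap of the real data was not counted. The simulations thus do not show how many of the 539 or 227 genes arise by chance. The mdEM libraries were too few to be split between the comparisons, so part of the excess in the same direction may come from the shared controls and shared deviations. Without mdEM replicate 1 the counts were 341 and 138, without mdEM replicate 3 121 genes were in opposite directions, and without distal cap replicate 1 148. Without replicate 2 of every group 2884 genes were in the same and 703 in opposite directions, and with a term for 2 classes of libraries 947 and 403. The counts without replicate 2 cannot be told apart from the replicate 2 axis, on which mdEM is opposite to both domains. Those of the main fit may be partly mixed with it.

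Dental mesenchyme of day 17 had higher WNT target genes and several higher tooth mesenchyme genes than the proximal-oral aggregates it was grown from. This comparison asks what changed with a GSK-3 inhibitor and activin A in the medium, without BQ-123 and LDN193189, and over 4 further days, which cannot be separated. AXIN2, a direct WNT target, rose 3.74-fold from 23.6 ± 2.79 to 88.4 ± 40.8 CPM. NKD1, which restrains WNT signalling, rose 6.24-fold from 47.1 ± 6.97 to 294 ± 135 CPM. MSX1 rose 30.2-fold from 0.941 ± 0.0156 to 28.7 ± 13.8 CPM. BMP4 rose 8.08-fold from 10.6 ± 1.52 to 85.6 ± 24.4 CPM, and INHBA, which encodes an activin subunit, 12.4-fold from 8.63 ± 0.596 to 107 ± 29.6 CPM. BARX1 fell 2.61-fold from 596 ± 25.2 to 228 ± 32.2 CPM.

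The WNT response list had 10 of 12 tested members higher and 0 lower over all genes, and 10 and 0 adjusted over the list alone and passed (camera adjusted p = 0.0270), but not without mdEM replicate 2 (0.0637), nor with the replicate number as a block in the 9 day 13 and day 17 libraries (0.194) or without replicate 2 of every group (0.140), in a range of 0.0188 to 0.194. NKD2 rose from 44.9 ± 5.32 to 291 ± 71.1 CPM. APCDD1 rose from 164 ± 39.3 to 799 ± 371 CPM and TNFRSF19 from 56.6 ± 8.37 to 278 ± 19.7 CPM. LEF1, a transcription factor of the pathway, rose from 1.12 ± 0.497 to 3.35 ± 0.901 CPM (edgeR adjusted p = 0.0248), but was not called without proximal-oral replicate 1 (0.128) or 3 (0.102) or dental mesenchyme replicate 2 (0.103) or 3 (0.0555), in a range of 0.00289 to 0.128. The dental mesenchyme list had 8 of 15 tested members higher and 1 lower over all genes, and 9 and 2 adjusted over the list alone (camera adjusted p = 0.0596), and passed without NCC replicate 1 (0.0356) or proximal-oral replicate 1 (0.0415), in a range of 0.0356 to 0.274. LHX6 rose from 28.9 ± 6.55 to 140.0 ± 28.0 CPM. LHX8 rose from 74.8 ± 20.1 to 275 ± 27.8 CPM and RUNX2 from 18.1 ± 4.22 to 56.4 ± 11.3 CPM. Not called were PAX9 at 8.25 ± 2.50 and 11.4 ± 6.66 CPM in proximal-oral and dental aggregates, FGF10 at 9.71 ± 1.64 and 5.70 ± 1.28 CPM and TNC at 326 ± 55.7 and 548 ± 138 CPM. TNC (edgeR adjusted p = 0.190) was called without replicate 2 of every group (0.0147), in a range of 0.0147 to 0.457. FGF3, DSPP, DMP1 and SP7, the last 3 genes of mineralising cells, had too few counts to be tested.

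The odontoblast and osteoblast list had 3 of 5 tested members higher and 0 lower over all genes, and 3 and 0 adjusted over the list alone (camera adjusted p = 0.168). COL1A1 was at 779 ± 94.3 and 1658 ± 331 CPM. In the activin and TGF-beta response list there were 4 of 9 tested members higher and 1 lower over all genes, and 4 and 1 adjusted over the list alone (camera adjusted p = 0.419). Cartilage genes counted 1 of 15 tested members higher and 7 lower over all genes, and 1 and 8 adjusted over the list alone (camera adjusted p = 0.0703). SOX6 fell from 80.1 ± 18.2 to 11.4 ± 6.78 CPM and COL2A1 from 860.0 ± 23.6 to 429.9 ± 88.7 CPM. The cartilage list passed without NCC replicate 1 (0.0356) or dental mesenchyme replicate 3 (0.0433), and with no filter (0.0415), in a range of 0.0356 to 0.352. The Hedgehog response list had 0 of 7 tested members higher and 3 lower over all genes, and 0 and 3 adjusted over the list alone (camera adjusted p = 0.273). HHIP fell from 29.7 ± 5.10 to 12.0 ± 2.46 CPM. The fibrillar matrix list had 7 of 14 tested members higher and 0 lower over all genes, and 8 and 0 adjusted over the list alone (camera adjusted p = 0.198). LUM rose from 790.0 ± 244 to 1992 ± 97.5 CPM and the cross-linking enzyme gene LOX from 23.1 ± 2.61 to 127 ± 14.8 CPM. Hypoxia and glycolysis genes counted 10 of 14 tested members higher and 0 lower over all genes, and 12 and 0 adjusted over the list alone (camera adjusted p = 0.166, 0.0209 without distal cap replicate 2, 0.0209 to 0.428 over its alternatives). ADM rose from 3.89 ± 1.84 to 29.8 ± 5.47 CPM. The endothelial list counted 0 of 6 tested members higher and 2 lower over all genes, and 0 and 5 adjusted over the list alone (camera adjusted p = 0.0658, 0.0393 without distal cap replicate 2, 0.0393 to 0.204 over its alternatives). The DLX and endothelin response list counted 0 of 12 tested members higher and 2 lower over all genes, and 0 and 6 adjusted over the list alone (camera adjusted p = 0.189, 0.0356 without NCC replicate 1, 0.0356 to 0.410 over its alternatives). The anterior neural identity list counted 2 of 8 tested members higher and 0 lower over all genes, and 4 and 0 adjusted over the list alone (camera adjusted p = 0.0781, 0.0466 without mdEM replicate 3, 0.0466 to 0.203 over its alternatives).

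LGR5, a WNT target and receptor gene, rose from 0.888 ± 0.687 to 60.1 ± 63.5 CPM, among the largest rises. WIF1, a secreted WNT inhibitor, rose from 2.02 ± 1.29 to 77.8 ± 58.7 CPM, EPYC from 2.23 ± 1.80 to 62.6 ± 28.96 CPM, CBLN4 from 0.502 ± 0.228 to 26.8 ± 13.3 CPM and CH25H from 0.387 ± 0.282 to 15.2 ± 3.36 CPM. The largest falls were those of PLD5, from 46.5 ± 3.38 to 1.04 ± 0.402 CPM, PCDH20, from 50.7 ± 9.11 to 1.13 ± 0.708 CPM, the thyroid hormone deiodinase gene DIO3, from 43.3 ± 16.9 to 1.495 ± 0.824 CPM, PAMR1, from 34.0 ± 6.45 to 1.46 ± 0.824 CPM, and ANGPTL1, from 26.3 ± 6.39 to 1.12 ± 0.728 CPM. GNAS, at 244 ± 27.6 and 9.77 ± 1.49 CPM, is uncertain, because its locus carries overlapping and antisense transcripts that these counts may not separate. Leaving out 1 library moved these fold changes by more than 1.5 times, on the log2 scale: LGR5 was 6.12 and 6.90 without proximal-oral replicate 2 and 4.76 without dental mesenchyme replicate 2, WIF1 was 5.29 and 4.47 without dental mesenchyme replicate 2, EPYC was 4.85 and 5.69 without proximal-oral replicate 2.

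edgeR called 1639 genes, 907 higher and 732 lower in dental mesenchyme. Of these, 848 changed at least 2-fold (471 up, 377 down). Camera called 1 of 28 lists. Fewer were called without proximal-oral replicate 1 (813, of which 517 at least 2-fold), proximal-oral replicate 3 (905) or dental mesenchyme replicate 2 (1011), and 3368 with the replicate number as a block in the 9 day 13 and day 17 libraries, where camera called 0 lists (smallest adjusted p = 0.194, 4 lists at an unadjusted p under 0.05). With the 2-class term 3031 genes were called. With replicate 2 of every group left out edgeR called 4088 genes and camera 0 lists. There were 6 lists at an unadjusted p under 0.05, with 12 called at the preset correlation and 20 by fry.

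**Figure D3:**
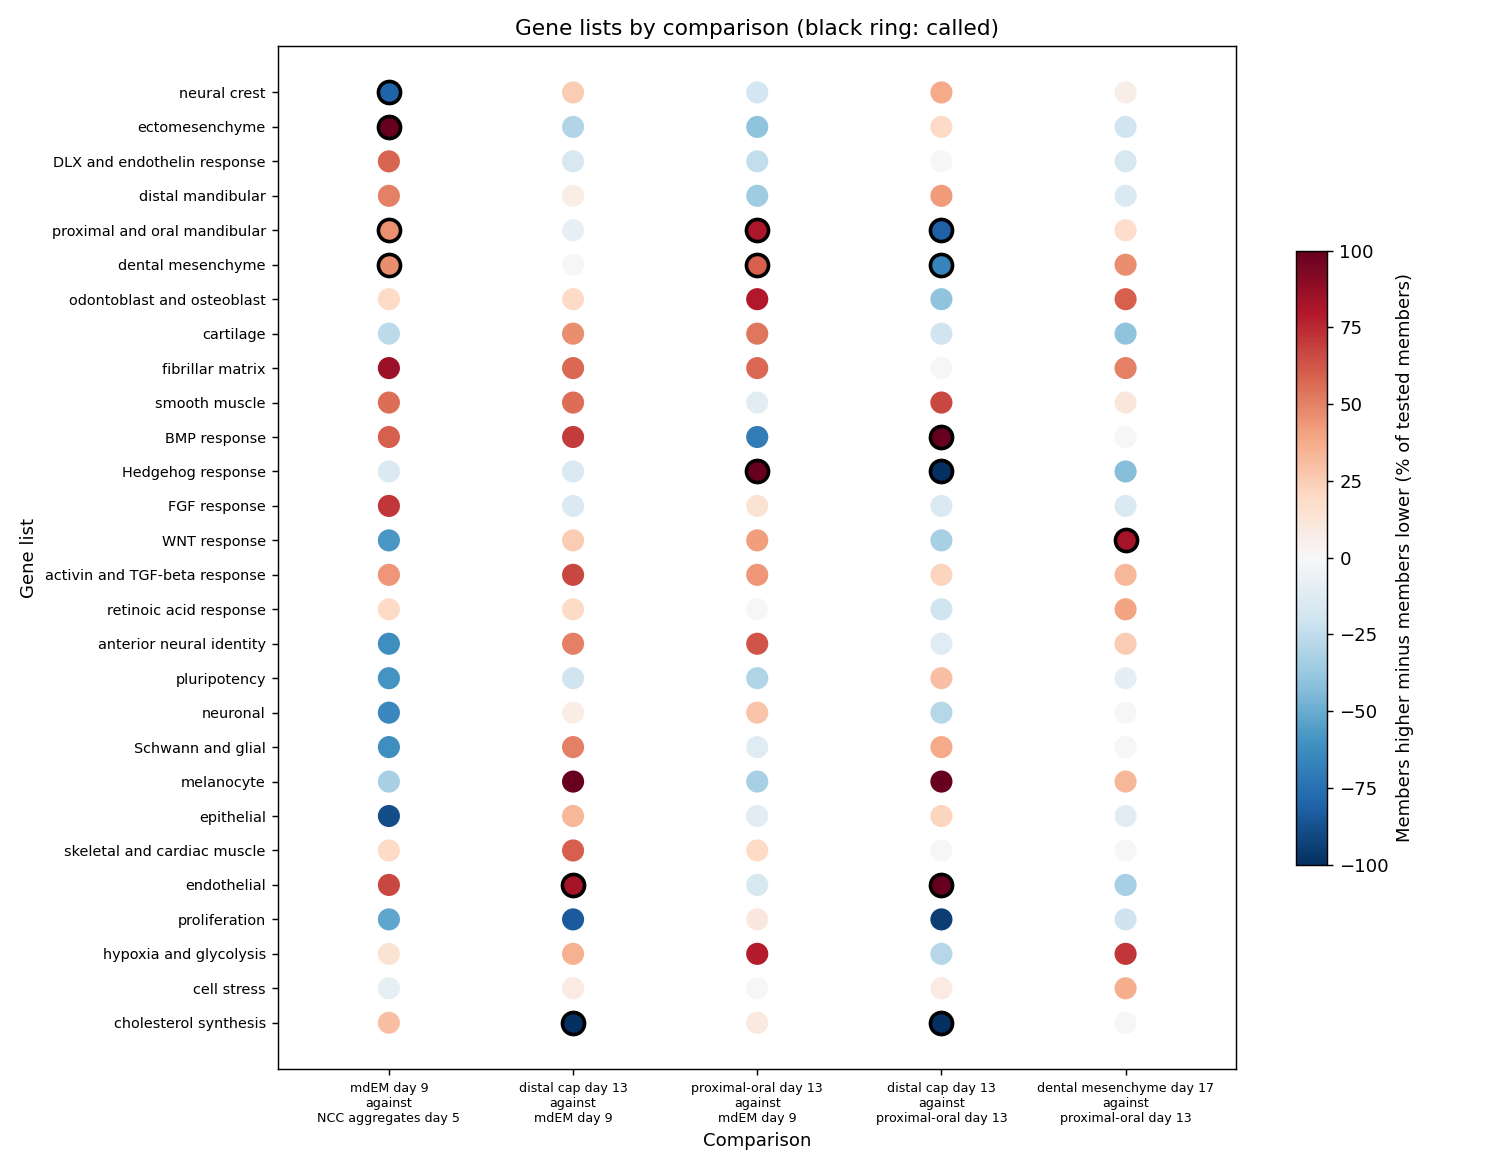
Each point is 1 of 28 gene lists (y axis) in 1 of 5 comparisons (x axis), coloured by members called higher minus members called lower as a percentage of tested members, with a black ring where camera called the list. Cholesterol synthesis is at 10 of 10 members lower in the distal cap in both of its comparisons, and 4, 2, 3, 6 and 1 lists carry a ring from left to right.

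Some uncalled lists had a median, a mean and a test statistic that differed in sign, so no direction is read from them. These were the cartilage, retinoic acid response, hypoxia and glycolysis, and Hedgehog response lists in mdEM against NCC aggregates, and the DLX and endothelin response, proximal and oral, dental mesenchyme, FGF response and cell stress lists in the distal cap against mdEM. They were also the neural crest, Schwann and glial, epithelial, and DLX and endothelin response lists in proximal-oral aggregates against mdEM, and the DLX and endothelin response, fibrillar matrix and cell stress lists between the day 13 domains. In dental mesenchyme against proximal-oral aggregates they were the distal mandibular, proximal and oral, and FGF response lists. The HOX genes were at or near the floor: 14 were measured, none passed the filter, and the highest single value in a library was 1.0 CPM.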

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

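The 2-class term, the block in 9 libraries and the fit of 10 libraries were chosen after the data were seen. The floor of 3 counts lies at 0.217 to 0.289 CPM at these depths, by totals before scaling, and no alternative varied depth. RLE scaling, upper-quartile scaling, no filter, the stricter filter, DESeq2, limma-voom and the fit of only the 6 libraries compared left each count of genes called within 1.5 times, and the largest shift of the median of all genes under another scaling was 0.05 on the log2 scale. Of 4492 values of named genes under alternatives, 4447 kept their direction and side of the threshold, 27 fell below it, 12 rose above it and 6 reversed.

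At the preset correlation camera called 18, 17, 14, 14 and 12 lists in the order of the comparisons, and fry, which does not compare a list with other genes, called 22, 20, 17, 18 and 14. With no filter camera called 2 lists in dental mesenchyme against proximal-oral aggregates. The cause was not tested. With the 2-class term edgeR called 3334 genes in the distal cap against mdEM and 3031 in dental mesenchyme against proximal-oral aggregates, with 403 in opposite and 947 in the same direction from mdEM. The term was built from the residuals of the same libraries, so a smaller spread follows in part from its construction.

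With replicate 2 of each group left out (10 libraries) edgeR called 6197 genes in the distal cap against mdEM, 1740 of them at least 2-fold, 6110 in proximal-oral aggregates against mdEM, 5629 between the day 13 domains and 4088 in dental mesenchyme against proximal-oral aggregates, with 703 in opposite and 2884 in the same direction from mdEM. Camera called 0 lists in all 5 comparisons (smallest adjusted p = 0.140), with 10, 5, 3, 9 and 6 at an unadjusted p under 0.05, 15, 12, 11, 15 and 12 at the preset correlation, and 26, 19, 26, 23 and 20 by fry. With fewer libraries the residual degrees of freedom are fewer. HAND2 in the distal cap against mdEM had a log2 fold change of 0.018 there and ID1 one of 0.30, both opposite in sign to those with all libraries and not called.

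With the replicate number as a block edgeR called 5487, 2412, 2691, 3520 and 1776 genes in the order of the comparisons, and in the block of 9 libraries 4950 between the day 13 domains and 3368 in dental mesenchyme against proximal-oral aggregates. Camera with the block called 1 list in mdEM against NCC aggregates, where neural crest (0.0538), proximal and oral (0.0557) and dental mesenchyme (0.0837) did not pass, and called smooth muscle in both comparisons of the distal cap (0.0471). The numbers were not taken to pair the samples in the comparisons with NCC aggregates and mdEM. Same-numbered libraries correlated there at -0.0740 to -0.365 and no library correlated best with its own number, while each did in the other comparisons. These values include the replicate 2 axis, on which mdEM has the opposite sign, so they cannot show that the numbers do not pair there. Besides the list calls given above and the cholesterol list between the day 13 domains, the block of 15 libraries changed no list call. The block of 9 libraries called 0 lists in its 2 comparisons (smallest adjusted p = 0.194, 9 and 4 lists at an unadjusted p under 0.05).

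Leaving out 1 library at a time gave 4375 to 5551, 1394 to 2459, 1694 to 2664, 2563 to 3592 and 813 to 1918 genes called, the lowest without NCC replicate 3, distal cap replicate 1, proximal-oral replicate 3, distal cap replicate 1 and proximal-oral replicate 1. For dental mesenchyme 517 to 1020 genes were at least 2-fold. Lists called ran from 2 to 7, 1 to 3, 3 to 6, 5 to 7 and 0 to 4, genes in opposite directions from 121 to 265 and in the same direction from 341 to 624. Genes reversed in sign without 1 library were not called with or without it, and their log2 fold changes over the libraries left out ran as follows. ID1 in the distal cap against mdEM ran from -0.26 to 0.17, and was 0.17 without mdEM replicate 2 and 0.02 without distal cap replicate 2. Between the day 13 domains SPRY4 ran from -0.72 to 0.14 without proximal-oral replicate 1. In dental mesenchyme against proximal-oral aggregates PAX9 ran from -0.069 without dental mesenchyme replicate 1 to 0.80. The cause was not tested.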

Other observations

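The tests on endothelial, muscle, sterol, scaling and proliferation genes were chosen only after the result was seen, and those on GC content, transcript length, differentiation stage and other splits before. Between day 5 and day 9, genes of several other cell states were lower in mdEM. The pluripotency list had 0 of 10 tested members higher and 6 lower over all genes, and 0 and 6 adjusted over the list alone (camera adjusted p = 0.133). LIN28A fell from 2783 ± 284 to 607 ± 112 CPM and SOX2 from 106 ± 29.7 to 2.36 ± 0.443 CPM. The anterior neural identity list had 0 of 8 tested members higher and 5 lower over all genes, and 0 and 6 adjusted over the list alone (camera adjusted p = 0.0703). LMX1B fell from 31.4 ± 3.50 to 0.679 ± 0.0413 CPM. The neuronal list had 1 of 14 tested members higher and 10 lower over all genes, and 1 and 10 adjusted over the list alone (camera adjusted p = 0.198). The epithelial list had 0 of 9 tested members higher and 8 lower over all genes, and 0 and 9 adjusted over the list alone (camera adjusted p = 0.145). The keratin gene KRT8 fell from 55.9 ± 18.1 to 14.3 ± 0.434 CPM. The WNT response list had 1 of 12 tested members higher and 8 lower over all genes, and 1 and 8 adjusted over the list alone (camera adjusted p = 0.189). NKD1 fell from 188 ± 65.8 to 17.8 ± 3.09 CPM. The BMP response list had 7 of 10 tested members higher and 1 lower over all genes, and 7 and 1 adjusted over the list alone (camera adjusted p = 0.267). ID1 rose from 30.8 ± 14.8 to 304 ± 94.0 CPM. CRABP2, a retinoic acid binding protein gene, fell from 2436 ± 346 to 194 ± 105 CPM. The retinoic acid response list had 2 of 5 tested members higher and 1 lower over all genes, and 2 and 1 adjusted over the list alone (camera adjusted p = 0.993). None of these lists passed.

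In the distal cap against mdEM the melanocyte list counted 3 of 3 tested members higher and 0 lower over all genes, and 3 and 0 adjusted over the list alone (camera adjusted p = 0.131). The regulator MITF rose from 1.24 ± 0.131 to 4.93 ± 1.27 CPM. In proximal-oral aggregates against mdEM the pluripotency list counted 1 of 10 tested members higher and 4 lower over all genes, and 1 and 7 adjusted over the list alone (camera adjusted p = 0.286). LIN28A fell from 607 ± 112 to 32.4 ± 2.77 CPM while SOX2 rose from 2.36 ± 0.443 to 23.6 ± 1.65 CPM. In dental mesenchyme against proximal-oral aggregates the cell stress list counted 4 of 11 tested members higher and 0 lower over all genes, and 6 and 2 adjusted over the list alone (camera adjusted p = 0.286). The retinoic acid response list counted 2 of 5 tested members higher and 0 lower over all genes, and 3 and 1 adjusted over the list alone (camera adjusted p = 0.153). No list named in this paragraph passed.

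Endothelial genes and GATA4, GATA5, GATA6 and TBX20 were high in the distal cap. The last 4 were picked from the largest differences, not from a list. MEF2C, also active in heart, went the other way against proximal-oral aggregates, at 0.243 ± 0.422 against 5.98 ± 2.83 CPM. It was near the floor in mdEM too, with 3 counts over the group. NKX2-5 was at 0.844 ± 0.264 against 1.60 ± 0.790 CPM in mdEM and not called. It was not lower than in proximal-oral aggregates, where it had 6 counts over the group. Neither gene thus went the other way against both groups. Of 14 further endothelial genes, 3 of them shared with the endothelial list, 11 could be tested and 100% of these were higher than in proximal-oral aggregates, PLVAP at 193, CD34 at 91.4, EMCN at 31.3 and CDH5 at 28.6 CPM, which is consistent with some endothelial cells among the aggregates. PECAM1 at 0.578, CLDN5 at 0.370 and VWF at 0.161 CPM were too low to be tested. Of 16 sarcomere genes, 3 of them in the muscle list, 11 could be tested, of which 45.5% were higher than in proximal-oral aggregates and 2 were lower. ACTC1 at 101 and TNNI1 at 54.9 CPM were among the higher ones. The lower ones were TNNT2 at 0.467 and ACTN2 at 0.912 CPM. The remaining tested members were not called. Among those too low to be tested, MYL7 was at 0.0243 and MYH7 at 0.259 CPM, and MYL2 had no count in any group. Cardiac muscle cells thus cannot be told apart from regulator genes raised in mesenchyme, because the members went both ways. A response of the mesenchyme itself to the distal medium stays open and was not tested.

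Cholesterol synthesis genes were low in the distal cap. The highest median log2 change of the list against mdEM under another scaling was -1.51. These scalings moved the median of all genes by at most 0.05, so they could not have brought the list near 0. A scaling factor shifts all genes of a library alike, however, and the median of all genes was 0.0226 against -1.55 for the list. These values argue against scaling as the source of the gap between the list and other genes. In mdEM against NCC aggregates the proliferation list had a median of -0.66 and the cholesterol list one of 0.28, which argues against slower proliferation alone. Of 14 further sterol genes, none in the list but 1 already seen to fall, 85.7% fell against mdEM, among them MSMO1 from 196 to 53.4 CPM and ACAT2 from 92.9 to 26.8 CPM, which is consistent with a wider fall of sterol-regulated genes. A direct effect of the higher BMP4 dose was not tested.

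Replicate 2 stood apart from the other pair in every group along 1 axis, in mdEM with the opposite sign. Across the 13087 genes with a GC value (91.6% of those tested; genes are not independent replicates), the loading followed transcript GC content with a Spearman's rho of -0.369. A technical difference that acts through GC content is a candidate explanation. Transcript length had a rho of -0.0488, within the bound set against it. The panel amplifies only a short stretch of each transcript, however, so this value does not decide on length. Differentiation stage cannot be told apart, since the largest rho with a stepwise log2 fold change was 0.140, between the bounds set for and against it. Genes of small RNAs, 93 tested, lay on the side of replicate 2 of the groups other than mdEM in 19.4% of cases against 51.2% of other genes. In mdEM, replicate 2 held 2.32% of its counts in them against 1.74% and 1.76% in the other pair, and in the other groups it held the lowest share.

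Each comparison of 3 with 3 libraries allows only 10 splits, too few for a share under 0.05. For genes called, genes called and at least 2-fold, and lists called, the real split was the only 1 of the 10 as large in all 5 comparisons. The real values were 5271, 2176, 2458, 3324 and 1639 genes, 3008, 1142, 1491, 2091 and 848 genes at least 2-fold, and 4, 2, 3, 6 and 1 lists. The highest other split gave 0 by edgeR or camera except 1 gene, called and at least 2-fold, in the distal cap against mdEM. Every other split mixes the 2 groups within a fitted group, which widens the spread. Their counts of 0 thus follow largely from how they are made and say nothing about chance. At an unadjusted p under 0.05 the highest other splits gave 2622, 3146, 2637, 1277 and 1873 genes and 1, 2, 3, 3 and 4 lists. The first 3 gene counts came from splits along the sides of the replicate 2 axis. These put mdEM replicates 1 and 3 with NCC replicate 2, and distal cap or proximal-oral replicates 1 and 3 with mdEM replicate 2. No other mixed split of these comparisons gave more than 852 genes. Where the numbers were taken to pair the samples, the 3 other splits that part all pairs and the 6 that part 1 pair all gave 0. For genes in opposite directions from mdEM, 1 of 100 splits of the 9 libraries, the real one, reached 227 (highest other 33). For genes in the same direction 4 of 100 reached 539, and the highest others, 1486, 781 and 758, took all proximal-oral or all distal cap libraries as the reference, which points to the structure of the samples. Every split that called any such gene kept a whole group as the reference. The others mix groups within a fit, which widens its spread, so how they are made fixes their count of 0. The bound set beforehand, a share under 0.05, was therefore wrong for these splits, and they say nothing about chance.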
